A study of Arabidopsis thaliana with 6 samples.

How the data were processed

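RNA was measured in seedlings of Arabidopsis thaliana, harvested 10 days after germination, on 6 single-colour Affymetrix ATH1 arrays. The arrays are labelled as biological replicates, 3 for the pvip1 pvip2 double mutant and 3 for the wild type Col-0. Per the labels' protocols, total RNA was extracted, cleaned on columns and turned into biotinylated cRNA. Wild-type roots were taken off before extraction, and the mutants were cut at their vestigial hypocotyl so that both genotypes were wounded. The make-up of the harvested tissue can therefore differ between the genotypes. In RNA of whole samples such a difference cannot be told apart from a change of expression within a tissue.

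The deposited table holds a log2 value for each of 22810 probe sets on each array, and the authors' method of summarising, background correction and normalization is not given in the sources used here. GCOS is named in the submitters' processing notes with no version. The base of the logarithm was read from the range of the values, since on base e or 10 the highest would lie far above the range of a 16-bit scanner. Many values lie in a dense group near the bottom of the scale, and the deposited table carries no detection call, so a large fold can depend on how the authors subtracted background. The deposited scanner setting files were used only to find batches. Linear signals averaged after a 2% trim ran from 87.1 to 91.0, a spread of 4.4%, which was under the 10% allowed, and the scaling was left as deposited. The number of arrays limits the precision: the median standard error of a log2 change was 0.203.

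Of the 22810 probe sets, 64 are controls and were left out of the tests. Names came from the platform annotation and from the TAIR10.1 gene table, which was used only for names and neighbours. Among the 22746 other probe sets, 13513 have 1 gene, 503 have several and 8730 are unnamed here. The gene table held the locus of 13436 of the 13513, and 11933 of the 13513 have only a locus code as a symbol. No coordinates are given, because the build behind the annotation is not given in the sources used here.

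Probe sets with a mean log2 signal under the 40th percentile, 3.81, were left out, and 13648 were tested. The filter uses the mean over both genotypes, so a rise in the mutant helps a weakly expressed gene to pass, and medians over tested members of a list can lie above those over all measured members. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The p values measure the spread among samples that the labels call biological replicates. A positive change means higher in pvip1 pvip2. A fold threshold of 2 gave the smaller count. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the list changed at all, so a difference between them is not a lost or gained call of the same question. Single control values were compared with a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3 arrays.

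The design, the 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the targeted genes and their paralogs, the 10 largest rises and 10 largest falls among called probe sets with 1 gene and no overlap between the genotypes, and up to 4 called members of a list that passed or had 3 or more called. Called members of the other lists and of the groups below were named after their values were seen. The lists hold 428 entries at 419 loci, and only 54 loci have a probe set with 1 gene here. The other loci can lie among the probe sets unnamed here or named with several genes, so they are not shown to be unmeasured. Below, a member counts as measured only if a probe set is named with it alone. With so few members named, most lists could not be tested as sets, and 8 had no named member: xylem and secondary wall, floral regulators, gibberellin and brassinosteroid synthesis, phosphate starvation, nitrate response, seed maturation and embryo, sugar starvation and heat shock. Further groups were therefore drawn up after the values had been seen: symbol stems shared by at least 10 named genes, and 16 gene families written from background knowledge of the loci. Of these, 9 families were prompted by the 30 largest changes in each direction or by the cell cycle result, and they stand in the closing section. The SAUR family, cysteine-rich receptor-like kinases and root hair-specific genes were among the other 7 and had no member tested.

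The replicate numbers in the labels were checked for pairing. Deviations from the genotype mean correlated between arrays of the same number at r = 0.592, 0.356 and 0.155 across probe sets, which are not independent. The pair with number 3 had the lowest of these. Between arrays of different numbers r ran from -0.453 to 0.248. The highest, of pvip1 pvip2 replicate 2 with Col-0 replicate 3, exceeded that of the pair with number 3. Every pair of the same number exceeded the r of 0.1 set as the rule for pairing. So did that pair and pvip1 pvip2 replicate 3 with Col-0 replicate 2 (0.114), so the rule does not establish the pairing for every number. Deviations from a genotype mean also cancel within the genotype, which ties these correlations together. They are therefore not separate evidence for each number. The main fit left the numbers out, and the fit with the number as a block was an alternative. The files show 2 fluidics stations: replicates 1 and 2 of both genotypes ran on the same station and replicate 3 of both on the other. Within the stations the mutant arrays ran on even-numbered modules and the Col-0 arrays on odd-numbered ones, so the module is confounded with the genotype. The arrays share 1 lot and 1 protocol.

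Other alternatives were scaling by medians or quantiles, no filter or a filter at the 60th percentile, pseudocounts of 16 and 64, other variance models, array weights and leaving out each array. The pipeline was tested on simulated data for the comparison of 3 with 3 arrays over 13648 probe sets. It recovered 2% of the simulated 1.5-fold changes, 28% of the 2-fold, 84% of the 4-fold and 96% of the 8-fold, and 6.2% of its calls were false. Only 50 probe sets were changed at each fold, with noise drawn independently, whereas 2803 were called in the data. The adjustment is stricter where fewer probe sets change, so these shares do not measure the power of the real comparison.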

Results

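The study set shoots of the pvip1 pvip2 double mutant beside Col-0, the standard laboratory accession, to find which transcripts differ between the genotypes. PVIP genes encode PHD-finger proteins, also known as OBERON proteins, that act in the formation of the plant's meristems. Each genotype was represented by 3 arrays, and each array gave a log2 signal for 22746 probe sets other than controls. Correlations between arrays ran from 0.976 to 0.988 within a genotype and from 0.932 to 0.962 between genotypes, across probe sets. At most 24 probe sets had exactly equal values in any pair of arrays, as deposited and without rounding.

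The targeted genes were examined first. OBE1 (AT3G07780), a PVIP gene under its other name, gave log2 signals of 2.54, 2.61 and 2.53 in the mutant arrays, at the bottom of the scale. It stood at 5.08 and 5.17 in Col-0 replicates 2 and 3 but at 2.42 in the array labelled Col-0 replicate 1, which goes against that label. The change of -1.66 (SE 0.63) was not called (adjusted p = 0.1285 without the level filter, which OBE1 did not pass), and the genotypes overlapped. With the replicate number as a block the adjusted p was 0.0482, with array weights it was 0.0296, and without the array labelled Col-0 replicate 1 the change was -2.56 with an adjusted p of 0.000266. Over its 16 alternatives the adjusted p for OBE1 ran from 0.000266 to 0.466. The sources used here do not say which part of the gene is disrupted, so a probe outside that part would check nothing. OBE2, OBE3 and OBE4 have no named probe set here and were not analysed.

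**Figure D1:**
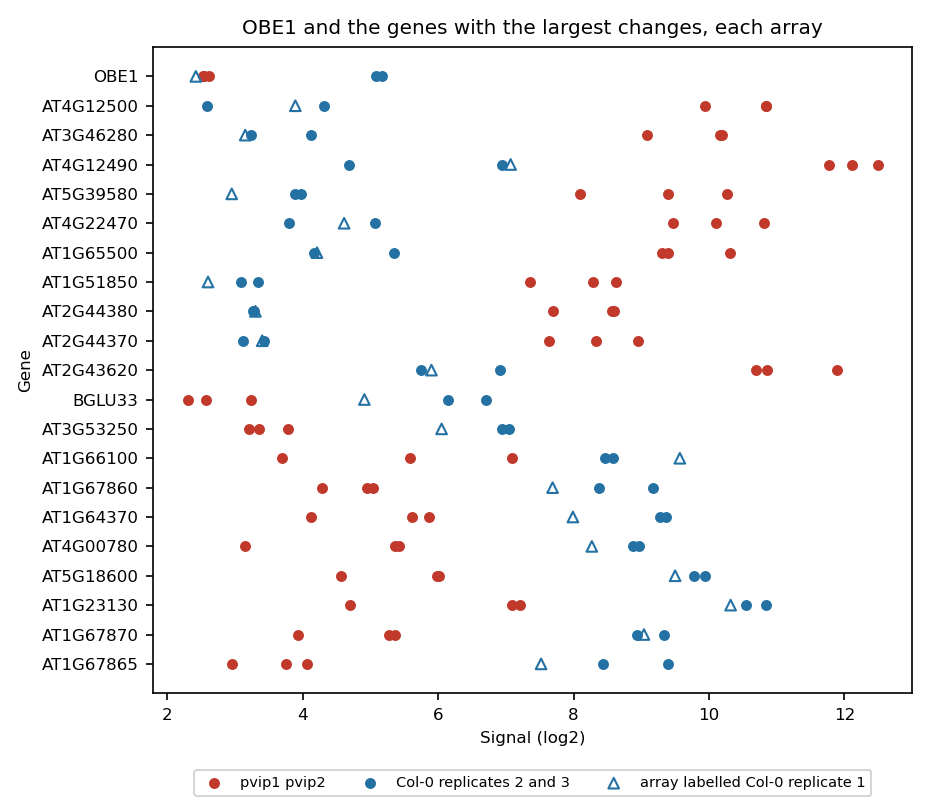
Log2 signal (x axis) of OBE1 and of the 10 genes with the largest rise and the 10 with the largest fall (y axis), with a point for each array: filled red for pvip1 pvip2, filled blue for Col-0 replicates 2 and 3, and an open triangle for the array labelled Col-0 replicate 1. OBE1 lies at 2.42 in that array, beside the mutants, while the other 20 genes were chosen for no overlap between the genotypes and therefore say nothing about that array's label.

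The largest rises in the mutant shoots included genes of lipid transfer proteins, a peroxidase, a chitinase and a receptor kinase. AT4G12500 rose by 6.94 on the log2 scale (SE 0.45, adjusted p = 0.0001151), from between 2.59 and 4.32 in the Col-0 arrays, and its neighbour AT4G12490 rose by 5.89 (SE 0.59). Both encode lipid transfer proteins of the EARLI1 type, and AT4G22470, a hybrid proline-rich protein of the same class, rose by 5.64 (SE 0.41). AT5G39580, a class III peroxidase of the cell wall, rose by 5.66 (SE 0.53), AT2G43620, a chitinase, by 4.97 (SE 0.39), and AT1G51850, a leucine-rich repeat receptor kinase, by 5.08 (SE 0.34). The C1-domain genes AT2G44380 and AT2G44370 rose by 5.01 and 4.99, and AT3G46280 and AT1G65500 by 6.32 and 5.10. AT4G12500, AT3G46280, AT5G39580, AT1G51850, AT2G44380 and AT2G44370 had Col-0 means under 3.81, the level of the filter, so the size and order of their changes depend on the authors' handling of background.

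The largest fall was that of AT1G67865, whose change was -4.86 (SE 0.48, adjusted p = 0.0005476), from 8.45 in Col-0 to 3.59 in the mutant. Its neighbours AT1G67870 and AT1G67860 changed by -4.26 (SE 0.37) and -3.66 (SE 0.38). AT5G18600, a CC-type glutaredoxin, changed by -4.22 (SE 0.38), AT1G66100, a thionin, by -3.42 (SE 0.75), and BGLU33, a beta-glucosidase, by -3.23 (SE 0.45). AT1G23130, AT4G00780, AT1G64370 and AT3G53250 changed by -4.24, -4.06, -3.68 and -3.24. AT1G67865, AT3G53250 and BGLU33 had mutant means under 3.81, and the size of their changes depends on background in the same way.

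In total 2803 of 13648 probe sets were called (20.5%), 1417 higher and 1386 lower in the mutant. With the replicate number as a block 4129 were called (30.3%), 1973 higher and 2156 lower, so the balance of directions depends on the fit. Of the 1576 called and changed at least 2-fold, 956 were higher and 620 lower, and changes of at least 16-fold were 42 rises and 5 falls. Of the 42 rises, 18 belong to probe sets unnamed here. The genotypes did not overlap in 2800 of the 2803, and in 39.2% of all tested probe sets, against 10% by chance. The main count of 2803 became 2611 with the fluidics station as a block, and 978 with the 2 arrays of each genotype on the first station alone. The second station held 1 array of each genotype, which allows no test. All mutant arrays ran on even-numbered modules of the stations and all Col-0 arrays on odd-numbered ones, so an effect of the module and the genotype cannot be told apart. Without the array labelled Col-0 replicate 1 the count was 2452, and without Col-0 replicate 3 it was 1877. It dropped below the main count by over 1.5 times without Col-0 replicate 2 (1654), pvip1 pvip2 replicate 2 (1752) or pvip1 pvip2 replicate 3 (1821).

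**Figure D2:**
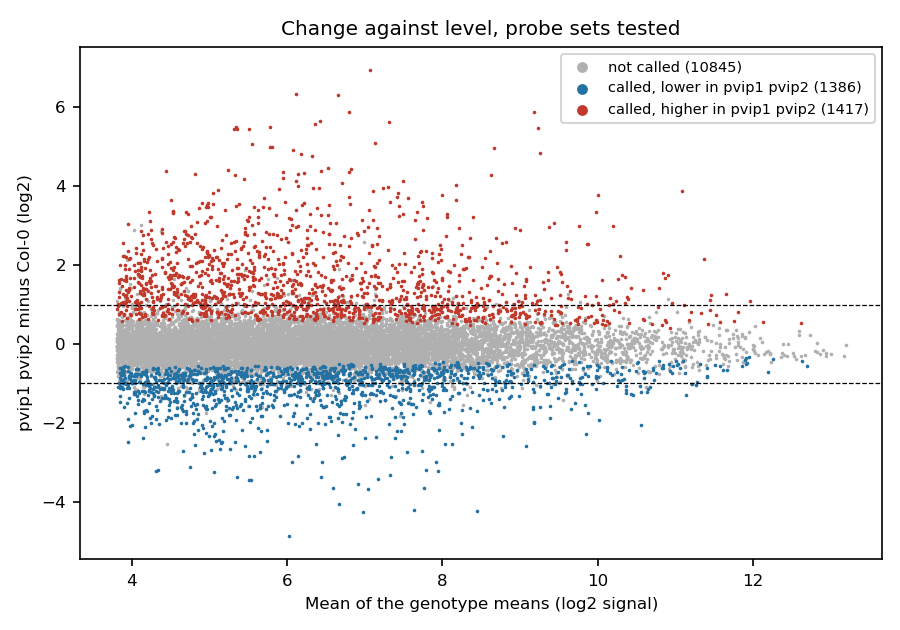
Log2 change, pvip1 pvip2 minus Col-0 (y axis), against the mean of the genotype means in log2 signal (x axis) for the 13648 probe sets tested, with called rises in red, called falls in blue and the others in grey. Dashed lines mark a 2-fold change, and rises reach 6.94 while falls reach -4.86.

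Among the fixed lists, genes of photosynthesis were lower in the mutant. All 6 tested members had a negative change, with a median of -0.39, and the list shifted as a set (camera adjusted p = 0.0198 over the 2 lists tested). With an estimated correlation the adjusted p was 0.208, without a trend in the variance model it was 0.0526, and without the array labelled Col-0 replicate 1 it was 0.0884 (0.00282 to 0.208 over the list's alternatives). PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis, was the only member called, at -1.13 (SE 0.18, adjusted p = 0.004644), and 3 members were lower when adjusted over the list alone. PRK, the phosphoribulokinase of the Calvin cycle, stood at -0.59 (adjusted p = 0.1481, or 0.01148 with the replicate block and 0.0279 without pvip1 pvip2 replicate 1). SBPASE, another Calvin cycle enzyme, stood at -0.44 (adjusted p = 0.3233, or 0.04089 with the block), and LHCB4.1, PSAE-1 and RCA lay between -0.33 and -0.27. LHCB4.1 had an adjusted p of 0.05534, or 0.0424 with a filter at the 60th percentile and 0.0425 with a pseudocount of 64.

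All 3 tested genes of the cell cycle list fell, and all 3 did so when adjusted over the list alone. Over so few genes that adjustment is milder than the one over all tested probe sets, so it adds no support. The mitotic kinases AUR1 and AUR2 changed by -1.08 (SE 0.28, adjusted p = 0.03018) and -1.18 (SE 0.28, adjusted p = 0.02207). MCM7, a subunit of the replication helicase named PRL in the gene table, changed by -0.88 (SE 0.20, adjusted p = 0.01943). These calls were lost with fewer arrays: without Col-0 replicate 3 the adjusted p values were 0.0907, 0.0741 and 0.0641, and without Col-0 replicate 2 they were 0.0996, 0.057 and 0.0709. The changes of AUR1, AUR2 and MCM7 without Col-0 replicate 3 were -1.008, -1.045 and -0.831. That of AUR1 was -0.785 without pvip1 pvip2 replicate 3. AUR1 was also not called without pvip1 pvip2 replicate 3 (0.0637), nor MCM7 without pvip1 pvip2 replicate 1 (0.0505) or 2 (0.0703). Calls of AUR1, AUR2 and MCM7 were lost on the first station alone (0.16, 0.113 and 0.0536).

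Of 5 tested genes of water deficit and abscisic acid, COR15B and COR47, which encode proteins made in cold and drought, fell. COR15B changed by -2.49 (SE 0.46, adjusted p = 0.007989) and COR47 by -1.002 (SE 0.23, adjusted p = 0.01936). The same 2 were lower when adjusted over the list alone, a milder adjustment over 5 genes. COR47 was not called without pvip1 pvip2 replicate 2 or 3 or without Col-0 replicate 2 or 3 (adjusted p from 0.0507 to 0.067), nor on the first station alone (0.128). COR15A stood at -1.40 and LEA4-5 at 0.98, with adjusted p values of 0.1332 and 0.2522, or 0.01249 and 0.02096 with the replicate block. Without pvip1 pvip2 replicate 1 the change of COR15A was -2.01 (adjusted p = 0.0265). The list did not shift as a set (adjusted p = 0.198, or 0.499 with an estimated correlation), except without pvip1 pvip2 replicate 1 (0.0376).

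Of 4 tested early auxin response genes, IAA29, a repressor of auxin signalling, fell at -1.95 (SE 0.33, adjusted p = 0.00595), also over the list alone. GH3.5, an auxin-conjugating enzyme named WES1 in the gene table, stood at -0.89 (adjusted p = 0.2288, or 0.01025 with the replicate block and 0.0493 with the station as a block), HAT2 at -0.50 and GH3.3 at 0.12. The iron regulator BHLH101 fell at -2.44 (SE 0.48, adjusted p = 0.01054), while PYE stood at 0.20. PDF1.2, a plant defensin induced by jasmonate, fell at -1.48 (SE 0.29, adjusted p = 0.01106), and WRKY53, a transcription factor of defence and senescence, rose by 1.27 (SE 0.21, adjusted p = 0.005013). Each of these lists had 1 member called, which was also called over the list alone. Over 4 or fewer tested genes that adjustment is milder than the one over all tested probe sets, so it adds no support. The lists of PDF1.2 and WRKY53 had 1 tested member each, so their p values stayed unadjusted there. The stomatal regulators FAMA (FMA in the gene table) and SPCH stood at -0.60 and -0.59, with adjusted p values of 0.05761 and 0.05128, or 0.03694 and 0.042 with the replicate block. Both were lower when adjusted over the 2 tested genes of their list alone, a milder adjustment.

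PYK10, a beta-glucosidase abundant in roots and the only tested root marker, rose by 1.76 (SE 0.10, adjusted p = 8.862e-05), from 10.02 to 11.78. The root hair expansins EXPA7 and EXPA18 lay below the level filter, at 0.33 and 0.21. Both were highest in pvip1 pvip2 replicate 2 (4.29 and 4.23), against 3.21 to 3.35 and 3.1 to 3.63 in the other arrays. No member was called among the 2 tested genes of auxin transport, synthesis and perception (YUC2 and YUC6), the 2 of vascular patterning (PHV and LHW), the 2 of flavonoid and anthocyanin synthesis (DFR and UF3GT), or the single tested genes of the shoot meristem (YAB3), hypoxia (HRA1) and the circadian clock (GI). The 1 reference gene measured stood at -0.21. Lists of cytokinin response, root meristem identity, sulfate starvation and trichomes had no member above the level filter. Without that filter BGLU28, of the sulfate starvation list, was called higher at 1.26 (SE 0.30, adjusted p = 0.02794).

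Groups formed by a shared symbol were drawn up after the values were seen. Their adjusted p values were computed in 1 pool with the gene families, including those prompted by the largest changes. The low p values of those families lowered the adjusted p of the UGT, CYP and TRM groups, and the calls were not recomputed without them. A call in that pool therefore does not establish a shift of the symbol groups taken by themselves. Unadjusted camera p values were 0.00679 for the UGT group, 0.0165 for the CYP group and 0.0155 for the TRM group. Among 28 tested UGT genes, which encode glycosyltransferases of small molecules, 7 rose and 1 fell. The direction of the group was upward (adjusted p = 0.0281 in that pool, or 0.278 with an estimated correlation). UGT72E1 rose by 3.07 (SE 0.17), UGT71C2 by 2.79 (SE 0.25) and UGT76B1 by 2.77 (SE 0.36), and UGT71C4 fell at -0.86. The call of the UGT group was lost without pvip1 pvip2 replicate 1 (0.0786), with a filter at the 60th percentile (0.126) and on the first station alone (0.0537). Among 13 tested CYP genes, 5 rose and 1 fell (adjusted p = 0.048, or 0.0612 with the block and 0.476 with an estimated correlation). All 6 were cytochrome P450 genes of the CYP71B group, led by CYP71B23 with a rise of 4.36 (SE 0.41). CYP59 and CYP71 carry the same stem but encode cyclophilins. Of 7 TRM genes, TRM22 and TRM15 fell at -1.75 (SE 0.17) and -0.68 (SE 0.17), and all 7 changes were negative (adjusted p = 0.048, or 0.0765 with the block and 0.279 with an estimated correlation). Calls of the CYP and TRM groups were both lost without the array labelled Col-0 replicate 1 (0.0589 and 0.0589), without pvip1 pvip2 replicate 1 (0.112 and 0.114) or 3 (0.0669 and 0.0697). The CYP call was also lost without Col-0 replicate 2 (0.0577), and the TRM call without Col-0 replicate 3 (0.0717), with array weights (0.0595), with the station as a block (0.0532) and on the first station alone (0.0972). Without the level filter the adjusted p was 0.0933 for the CYP group and 0.33 for the TRM group, and without a variance trend it was 0.0565 for the CYP group. Over all measured members, whether or not above the filter, the median change was 0.11 for 47 UGT genes (0.25 for the 28 tested), 0.04 for 26 CYP genes (0.49 for the 13 tested) and -0.23 for 15 TRM genes (-0.34 for the 7 tested). TRM82 has the same stem but belongs to a tRNA methyltransferase. Of the other 15 groups formed by a symbol and large enough to test, none shifted as a set with camera (lowest adjusted p 0.12, for IQD genes), fry called 3 of them (SCPL, TBL and IQD), and the GSTU and NET groups had too few tested members.

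Among gene families written down at the same stage and not prompted by the largest changes, 100 tested genes of cytosolic ribosomal proteins had a median change of 0.06, with 2 higher and 1 lower (adjusted p = 0.366), and 0 called either way when adjusted over the list alone. The 8 tested core histone genes all encode H2B, so the other core histones were not examined. Of these, AT2G37470 and HTB1 fell at -0.88 and -0.58, and the H2B genes did not shift as a set (camera adjusted p = 0.329). Further photosynthesis genes had 3 of 6 tested members lower, LHCB4.2 at -0.72 (SE 0.18), PSAN at -0.66 (SE 0.16) and PSBW at -0.51 (SE 0.14). As a set they had an unadjusted camera p of 0.0122. The adjusted p was 0.0444, or 0.679 with an estimated correlation and 0.0655 with array medians set equal. The pool for that adjustment held the families prompted by the largest changes, whose low p values lowered it, so the call does not stand by itself. That call was lost without a variance trend (0.0726), while fry, which asks another question, gave 0.0917. It was also lost without the array labelled Col-0 replicate 1 (0.125), without pvip1 pvip2 replicate 2 (0.0567) or 3 (0.0942), and on the first station alone (0.0537). Of 2 late embryogenesis abundant genes tested, none was called by limma over all tested probe sets, and 1, AT3G17520, was higher when adjusted over the list alone and had an unadjusted p under 0.05. AT3G17520 stood at 0.96 (SE 0.31, adjusted p = 0.06339, or 0.03573 with the replicate block). Without the level filter 2 of the 17 measured were called higher, LEA18 from 3.14 to 4.24 (adjusted p = 0.01105) and AT4G21020 from 2.37 to 2.86 (adjusted p = 0.02548).

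**Figure D3:**
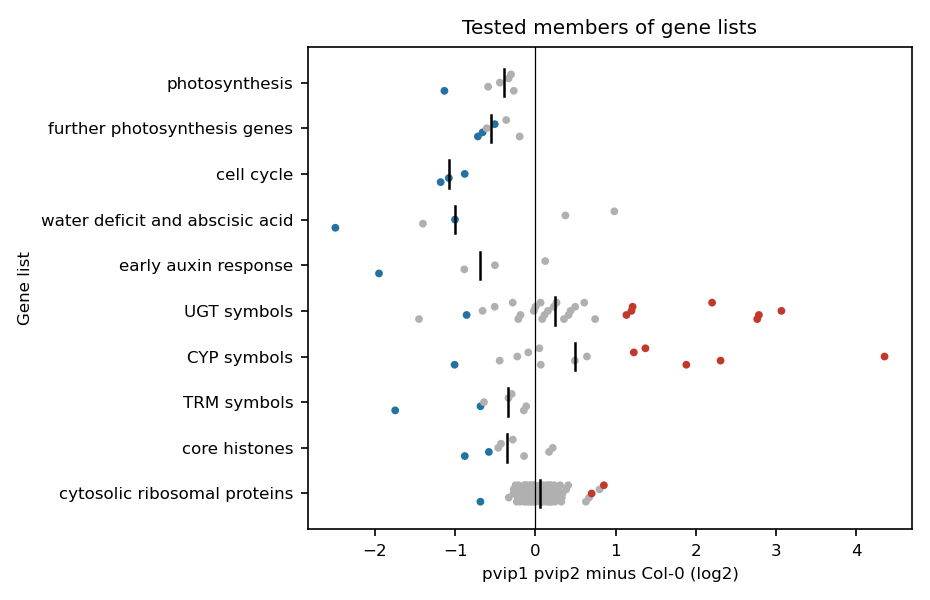
Log2 change, pvip1 pvip2 minus Col-0 (x axis), of each tested member of 10 gene lists (y axis), in red where called higher, in blue where called lower and in grey where not called, with the list's median as a black line. The photosynthesis and cell cycle medians lie at -0.39 and -1.08, and that of cytosolic ribosomal proteins at 0.06. The core histones shown are H2B genes alone.

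The controls on the arrays gave a measure of RNA quality. In Col-0 replicate 3 the 3' end of GAPDH exceeded its 5' end by 2.31 on the log2 scale, against 0.55 to 1.08 in the other 5 arrays. The mean difference over GAPDH, actin and ubiquitin was 2.90 there and between 1.95 and 2.07 elsewhere. The ribosomal RNA control was at 10.15 in that array and between 5.96 and 7.67 in the others. Between genotypes the GAPDH difference was 0.78 ± 0.20 (SD, n = 3) in the mutant and 1.45 ± 0.75 (SD, n = 3) in Col-0 (exact permutation p = 0.1, the smallest possible here). Actin and ubiquitin differed by -0.06 and -0.13 (exact permutation p = 1 and 0.3). Of the other 8 controls, thr, bioC and bioD also reached p = 0.1 in the exact permutation test, unadjusted for the 11 controls compared, with mutant minus Col-0 at -0.79 for thr and at 0.22 and 0.16 for bioC and bioD.

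**Figure D4:**
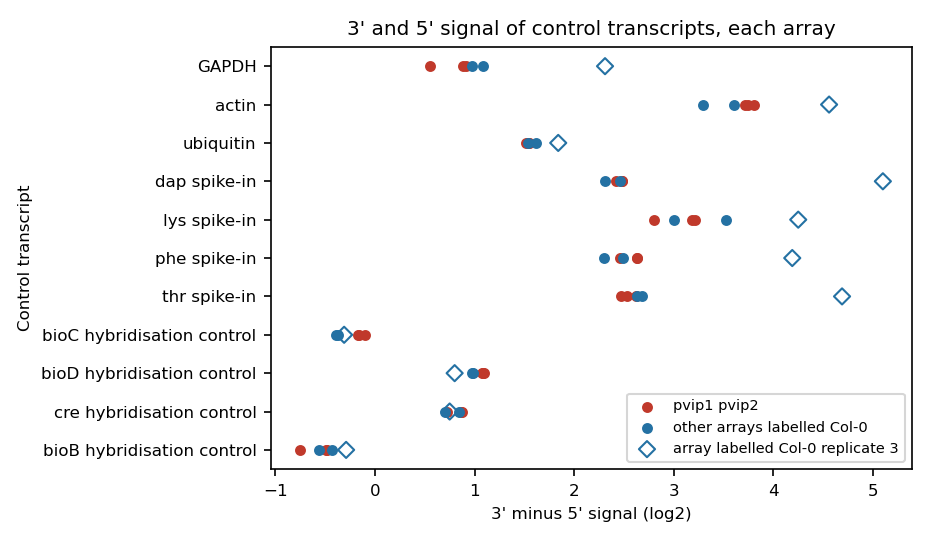
Log2 signal at the 3' end minus that at the 5' end (x axis) of 11 control transcripts (y axis), with a point for each array: red for pvip1 pvip2, blue for the other arrays labelled Col-0, and an open diamond for Col-0 replicate 3. The diamond lies at 2.31 for GAPDH and above the other arrays for all 3 plant transcripts and 4 spike-ins, while among the hybridisation controls it lies below the others for bioD (0.80), above them for bioB (-0.29) and among them for bioC and cre.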

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

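The arrays of the first station alone, and the station block for all but the count of calls, were chosen after seeing the data. The count of 2803 called probe sets was 4129 with the replicate block, 1826 with a filter at the 60th percentile (fewer probe sets tested), 1224 at an adjusted p under 0.01 and 978 on the first station alone (fewer arrays). Leaving out single arrays gave 1654 to 2741. The 1576 called and changed at least 2-fold became 942 with that filter, 1050 and 542 with pseudocounts of 16 and 64, which shrink the folds of low signals by construction, and 948 on the first station alone. Leaving out single arrays gave 1321 to 1785. Without detection calls, folds of genes near the floor of the scale are the least certain.

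Of 2 fixed lists tested, 1 shifted; the count was 0 with eBayes without a trend, 0 with an estimated correlation, and 0 to 2 without single arrays, and the cause was not tested. The OBE1 change of -1.66 passed the threshold with the replicate block (-1.66), with array weights (-2.05) and without the array labelled Col-0 replicate 1 (-2.56), and ran from -2.56 to -1.19 without single arrays. A filter at the 60th percentile gave OBE1 no value.

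Of the recomputed values of the 20 largest changes and of the tested members of fixed lists, 933 stayed on their side of the threshold, 18 lost the call and 16 gained it. Among lists the counts were 265, 39 and 10, with fry counted as an alternative although it asks another question. Of the 18, 1 was among the 20 largest changes, AT1G66100 on the first station alone. No such gene or list reversed a call. Besides the values given with the results, the replicate block changed no other call of a named gene or list. Of the 2803 called, 2802 were called with the block too.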

Other observations

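The gene families, the tests of the low 5' signal, the test of a mislabelled sample, the tests of scaling and of the 3' shift for the peroxidases (which replace tests on members past the level filter) and the test of levels between probe sets that share a gene were chosen only after the results were seen. Of 24 tested class III peroxidases, which build and loosen cell walls, 15 rose and 3 fell, with a median change of 1.65 (camera adjusted p = 3.66e-06, 0.000111 without the genes seen first, and 0.194 with an estimated correlation). AT5G64120 rose by 4.84 (SE 0.28) and Prx37 by 4.42 (SE 0.43). Of 11 berberine bridge enzyme-like oxidases, 8 rose and 1 fell (adjusted p = 4.24e-06, 0.000111 without those seen first, and 0.194 with an estimated correlation), with AT5G44380 up by 4.45 (SE 0.39). Of 8 chitinases 5 rose and none fell (adjusted p = 5.76e-05, 0.00338 without those seen first, and 0.194 with an estimated correlation), with AT4G01700 up by 4.77 (SE 0.28) and AT1G02360 by 3.41 (SE 0.20). Of 7 leucine-rich repeat receptor kinases with a malectin domain, 6 rose and none fell (adjusted p = 3.18e-06, 0.000145 without those seen first, and 0.269 with an estimated correlation), with AT1G51790 up by 4.33 (SE 0.22). These counts leave out members under the level filter, which a rise helps a gene to pass. Over all measured members the median change was 0.30 for 55 peroxidases, 0.45 for 22 oxidases (2.44 for those tested), 0.23 for 14 chitinases (3.09 for those tested) and 0.05 for 33 kinases (2.78 for those tested). Called without the filter were 20 peroxidases higher and 2 lower, 9 oxidases higher and 1 lower, 5 chitinases higher and 9 kinases higher. Of 8 lipid transfer and hybrid proline-rich proteins, AT4G12500, AT4G12490 and AT4G22470 rose and the set was not called (adjusted p = 0.0581, 0.721 without those 3, and 0.446 with an estimated correlation). The 3 that rose are those seen first, and none of the other 5 was called by limma (1 had an unadjusted p under 0.05; median change -0.013). Camera called the set of 8 tested members without the array labelled Col-0 replicate 1 (0.0121), without Col-0 replicate 2 (0.0478) and without pvip1 pvip2 replicate 2 (0.0491). It also did so with quantile normalization (0.0468), with pseudocounts of 16 and 64 (0.0425 and 0.0424) and with array weights (0.0441). Over all 10 measured members without the level filter the set was called too (0.0275). Fry, which asks another question, gave 0.0066.

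Families that fell included the CC-type glutaredoxins, small redox proteins that act with TGA transcription factors. Of 8 tested, 6 fell and none rose (adjusted p = 0.0012, 0.0109 without those seen first, and 0.194 with an estimated correlation), with AT4G15690 at -2.39 (SE 0.39) and AT1G06830 at -2.26 (SE 0.19). The median change was -1.63 for the 8 tested and -1.35 over all 17 measured, of which 10 were called lower and 1 higher without the filter. Of 12 further mitosis genes, listed because of the cell cycle result, 8 fell and none rose (adjusted p = 3.91e-05, and 0.476 with an estimated correlation), with AT3G02640 at -1.86 (SE 0.25) and BUB3.1, a spindle checkpoint protein, at -1.15 (SE 0.18). Their median change was -1.01, and -0.68 over all 32 measured, of which 14 were called lower without the filter. Of 5 further DNA replication genes, limma called none, 1 (PSF2) had an unadjusted p under 0.05, and the set did not shift (adjusted p = 0.601). BCAT4 and AT2G31790, both of aliphatic glucosinolate synthesis, fell at -2.74 (SE 0.19) and -0.77 (SE 0.19).

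Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real split, gave as many calls: 2803 probe sets against at most 0 in any other, and for changes of at least 2-fold 1576 against 0, also in 1 of the 10. With 10 splits the share is never under 0.1, too few for a share under 0.05. Every other split also mixes the genotypes on both sides, so the genotype difference widens the spread within its groups and holds its calls down. The 0 is therefore no measure of what chance gives. At an unadjusted p under 0.05 the real split gave 4660 probe sets with limma and the others 20 to 904. The 3 other splits that also part all 3 replicate numbers gave 20 to 154, and the 6 that part 1 number gave 64 to 904.

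Col-0 replicate 3 had low 5' signal. Degradation of the plant RNA alone is argued against by the poly-A spike-ins, which are not plant RNA: their mean 3' minus 5' difference was 4.56, which is 1.82 above the highest of the other 5 arrays. Short products of the labelling reaction remain a candidate explanation, since plant controls and spike-ins all shifted upward while the mean over the 4 hybridisation controls, added after labelling, differed by -0.03 from that of the other arrays, with bioD below their range and bioB above it. No biological explanation was tested.

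OBE1 was at the floor in the array labelled Col-0 replicate 1. A mutant sample under a wild-type label is argued against: over 1587 probe sets called and changed at least 2-fold without that array, its median position between the other wild types (0) and the mutants (1) was 0.063, beside 0.039 and 0.058 for Col-0 replicates 2 and 3. The 95% bootstrap interval of 0.049 to 0.08 was taken over probe sets, which are not independent, and does not measure the spread between arrays. A step of the background correction at low signal stays open, because the count made to test it cannot decide. Of 3370 probe sets between 4.5 and 6 in the other wild types, 4 (0.12%) were under 3 in that array. OBE1 is itself among the 4, so the count partly holds the pattern it was meant to explain. The same test of the other wild-type arrays gave 0 and 1. A true difference in OBE1 between the plants was not tested.

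The rise of class III peroxidases was set against 3 technical explanations. Over all 55 measured members the mean change exceeded that of the other probe sets by 0.885 (SE 0.203 across genes, which are not independent). With quantile normalization it exceeded that by 0.899 (SE 0.202). This is hardly a test of scaling, since a shift of all probe sets alike cancels in this measure and the members moved by a median of only 0.023. Without Col-0 replicate 3 the excess was 0.873 (SE 0.21), which argues against its 3' shift. Root-type tissue in the mutant samples stays open, although Col-0 roots were removed: the 11 peroxidases known as root-specific had a median of 0.25 (SE 0.48), against 0.506 (SE 0.296) for the other 44. This comparison was corrected after its value was seen, since the others had at first held only genes past the level filter while the 11 had not. Past that filter the medians were 1.727 (SE 0.87, 4 genes) and 1.646 (SE 0.57, 20 genes), which decides nothing because a rise helps a gene to pass, while AT4G30170 and AT2G18980 of the 11 rose by 3.70 and 2.55 and the root marker PYK10 by 1.76. The genotype itself remains an untested explanation.

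As a hypothesis, a segment of another accession linked to OBE1 would raise the share of calls near it. Of the 50 nearest named and tested genes, 11 were called (22%), against 19.9% in the rest of chromosome 3, a ratio of 1.1 (one-sided permutation p = 0.413), which argues against a segment around OBE1 as a source of many calls. The surroundings of the other gene of the double mutant were not examined.

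Neighbouring genes may change together. Of 2142 adjacent pairs of tested genes, 65 were called in the same direction, 1.68 times the mean of 38.8 with shuffled positions (one-sided permutation p = 0.001 over 2000 shuffles), while 33 pairs were called in opposite directions against 38.4. Runs of 3 were AT1G61360 to AT1G61380, which rose, and AT1G67860 to AT1G67870 and AT5G17650 to AT5G17670, which fell. Signal shared between similar neighbours stays open: such pairs differed in wild-type level 0.94 times as much as other adjacent pairs (95% bootstrap interval 0.69 to 1.29). The prediction, written before that value was seen, was that shared signal would bring levels under 0.5 times as far apart. It was wrong, because 98 pairs of tested probe sets named with a gene in common, which share signal by design, differed 0.96 times as much as other adjacent pairs. Probe sequences were not used here.

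On the axis between the genotypes pvip1 pvip2 replicate 1 lay at 0.764, against 1.057 and 1.008 for replicates 2 and 3. The second principal component, with 17% of the variance, held 30.6 and 34.3 for the arrays labelled replicate 1 of the mutant and of Col-0, and negative scores for the others.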
